A study of Mus musculus with 12 samples.

How the data were processed

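Gene expression was measured with Affymetrix mouse arrays in 12 samples of BNL CL.2 cells, 3 per group, after 24 h of culture. RNA was extracted with the Qiagen RNeasy mini kit per the labels. The deposited values are log2 signals that the authors computed with RMA in the affy package, per the submitters' processing notes; the versions of RMA and affy are not given in the sources used here. The values ran from 2.42 to 14.6 and the array medians from 5.63 to 5.68, and no further scaling was applied. Across the 18194 genes tested, arrays of a group correlated at 0.997 to 0.998 and arrays of different groups at 0.996 to 0.999. At most 0.166% of probe sets had identical values in any 2 arrays. The number of arrays limits the precision.

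Of 45101 probe sets, 34958 had 1 gene symbol in the annotation used, 932 had several and 9211 had none, and the latter 2 kinds were left out. For each of the 9012 genes with more than 1 probe set, the probe set with the highest mean over the 12 arrays was kept, which gave 18194 genes. Groups and replicate numbers were taken from the sample titles.

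A linear model with 1 mean per group was fitted to the 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (4.90 prior degrees of freedom, median residual SD 0.109). Genes passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The 5 comparisons of 2 groups and the interaction were tested. Gene lists were tested against all other genes with limma camera at a preset correlation between genes of 0.01, adjusted over 39 lists: 33 of pathways, responses and regulators and 6 of cell type markers, with 695 of 760 entries found on the array. Adjusted p values within a list alone were also computed. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for the tables and plots.

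These tests, the lists, the rule for naming genes and the alternatives were set before the data were examined. The rule named, per comparison, the 10 genes with the largest changes in each direction among those past the threshold with the 3 arrays of a group above the 3 of the other. It also named up to 4 members of each list past the threshold, 17 fixed genes of iron handling, inflammation, macrophages and liver, and, where fewer than 5 genes passed, the 10 genes with the smallest unadjusted p. Genes named for passing with the replicate block, the average effects and the list tests of the interaction were chosen after the data were seen.

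Whether equal replicate numbers pair the arrays was checked from the residuals after group means were removed. The 18 same-number pairs correlated at 0.26 to 0.53 (median 0.33) and the 36 different-number pairs at -0.35 to -0.01 (median -0.17), and each of the 12 arrays was closest to an array of another group with its own number. Residuals sum to 0 within a group, so positive same-number correlations make the others negative. The replicate number was therefore also used as a block, an additive term of the model, with 4.48 prior degrees of freedom; the titles give the numbers but do not say what they stand for. Same-number residuals correlated more within an iron condition (median 0.431) than across (0.315), which an additive block does not model. With the block, SE and adjusted p of genes and lists may therefore be too small where arrays with and without iron are compared. Nothing in the sources used here says that replicates are separate cultures, so p values measure the spread between these samples.

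The alternatives set in advance were array weights, a fit to the arrays of the compared groups, leaving out genes with a mean below 6.82 (9097 kept), an estimated correlation between genes, the fry test, centring on the median, quantile normalization, other choices of probe set, the replicate block, leaving each of the 12 arrays out, a log2 change of at least 1, and moderation with a trend and robust. Combinations with the block were added after the data were seen. Leaving 1 array out of the fit without the block leaves unequal replicate numbers in the groups. Differences between replicate numbers then enter the changes and list calls, in each comparison. A count was said to move when it differed by more than 1.5 times. RNA quality was compared with two-sided exact permutation tests, whose smallest p for 3 arrays against 3 is 0.1.

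The fits were tested on simulated data with the layout of FAC against alone. Of 50 genes changed by 0.5, 1, 2 or 4, the fit without the block recovered 68%, 98%, 100% and 100%, and the fit with it 82%, 100%, 100% and 100%. Among the genes left unchanged in that comparison they called 1 and 8, and 0 of 18194 genes in a comparison with no change. Of 5 lists shifted by 0.3, 5 were recovered with the preset correlation, and 4 without and 5 with the block under an estimated correlation, with 0 other lists called. The genes changed by 1, 2 and 4 ease the adjusted p of those changed by 0.5, so the shares may overstate what the real fits recover. Beyond the replicate-number effects, noise was drawn separately for each gene. The simulation therefore does not test list calls that arise when the genes of a list vary together.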

Results

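Gene expression was measured on 12 Affymetrix mouse arrays in BNL CL.2 cells, a mouse liver cell line. The 4 groups of 3 arrays each followed 24 h of culture under different conditions. In the group called alone, further BNL CL.2 cells sat in a culture insert. In the group FAC, 100 micromolar ferric ammonium citrate, a soluble iron salt, was added. In the group RAW the insert held RAW 264.7 cells, a mouse macrophage line, and RAW_FAC combined the macrophages with the iron salt. Each array gave log2 values for 45101 probe sets, from 2.42 to 14.6 over the 12 arrays, with array medians between 5.63 and 5.68. The 18194 genes with a probe set of their own were compared. Changes are log2 differences between group means with n = 3 arrays per group, and their standard errors (SE) come from the fit named beside them. A same-number pair is 1 array from each of 2 groups with the same replicate number.

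The comparison of FAC with alone asked which genes of the liver cells changed with iron when no macrophages were present. Tfrc, which encodes the receptor that brings transferrin-bound iron into cells, fell by 1.25 ± 0.13 (SE with a replicate block), a 2.37-fold difference, and was lower in 3 of 3 same-number pairs and 6 of 6 probe sets (-1.54 to -0.27). Slc7a11, the subunit of the cystine-glutamate exchanger that imports cystine, rose by 0.83 ± 0.11 with the block. Blvrb, a reductase that acts on biliverdin, rose by 0.58 ± 0.06, Serpinb1b, a serine protease inhibitor, by 0.65 ± 0.08, and Sqor, a mitochondrial enzyme that oxidises sulfide, by 0.41 ± 0.05. The chemokine gene Ppbp fell by 0.56 ± 0.07. Each of these 6 genes moved the same way in 3 of 3 same-number pairs. A second probe set of Sqor gave -0.06. Without alone replicate 1, and without the block, the difference was 0.50 for Slc7a11, 0.39 for Serpinb1b and 0.14 for Sqor, and that of Sqor was 0.68 without FAC replicate 1 and 0.24 without FAC replicate 2. These fits leave unequal replicate numbers in the 2 groups, so differences between numbers enter the values. Over the 6 same-number pairs with iron, without and with macrophages, Slc7a11 changed by 0.55 to 1.13 and Sqor by 0.33 to 0.49.

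These 4 higher and 2 lower genes passed in limma with the replicate block, with adjusted p from 0.0242 for Tfrc to 0.0460 for Ppbp, and were named after their values were seen. Their SE and adjusted p may be too small, since same-number residuals correlated more within an iron condition (median 0.431) than across (0.315). The limma fit without a block, which was planned, called 0 of 18194 genes in either direction and gave Tfrc an adjusted p of 1.00. In that fit 551 genes had an unadjusted p under 0.05, against 909.7 expected by chance, and with the block 1196 did. The blocked count of 4 higher genes became 0 without alone replicate 1, alone replicate 2, FAC replicate 1, FAC replicate 2 or RAW replicate 3, and 1 without FAC replicate 3, RAW replicate 1, RAW_FAC replicate 2 or RAW_FAC replicate 3. It was 2 without alone replicate 3 or RAW replicate 2. The blocked count of 2 lower genes became 0 without alone replicate 2, FAC replicate 1, FAC replicate 2 or FAC replicate 3, and 1 without any single one of the other arrays. The 10 genes with the smallest unadjusted p without the block, none of them past the threshold, were Tfrc, Gclc, Vwa2, Cpn1, Srxn1, Cyp26b1, Dbp, Scn7a, Zfp750 and Nqo1.

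Among the gene lists fixed for this system, cholesterol synthesis was higher with iron, with a median change of 0.39 and 20 of 20 measured genes above 0 (limma camera adjusted p = 3.53e-23, and adjusted p = 0.267 with an estimated correlation). Its members Insig1, a sterol-responsive regulator, Mvd, which makes isopentenyl diphosphate, and Idi1, which isomerises it, had changes of 0.68 ± 0.20, 0.59 ± 0.21 and 0.55 ± 0.14 (SE without the block). Over all genes 0 of the 20 passed, and adjusted over the list alone 12 did, or 17 with the replicate block. The list of targets of NRF2, the transcription factor of the antioxidant response, had a median of 0.22 with 21 of 21 genes above 0 (adjusted p = 2.78e-15, and adjusted p = 0.267 with an estimated correlation). With the block it kept its call under an estimated correlation (adjusted p = 0.0298). Nqo1, a quinone reductase, changed by 0.52 ± 0.13 and Gclc, which makes glutathione's precursor, by 0.36 ± 0.08 without the block. Adjusted over the list alone 4 NRF2 targets passed, against 0 over all genes, and with the block 14 against 1, which was Slc7a11.

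The unfolded protein response list, chaperones and folding enzymes of the endoplasmic reticulum, had a median of 0.24 with 19 of 20 genes above 0 (adjusted p = 1.06e-05, and adjusted p = 0.754 with an estimated correlation). Fatty acid synthesis had a median of 0.14 with 15 of 16 genes above 0 (adjusted p = 0.000119, and adjusted p = 0.709 with an estimated correlation). Heme synthesis and breakdown had a median of 0.05 with 10 of 15 genes above 0 (adjusted p = 0.00383, and adjusted p = 0.246 with an estimated correlation). Its members included Hmox1, which opens the heme ring, at 0.50 ± 0.30, and the heme transporter gene Slc48a1 at 0.48 ± 0.16 (SE without the block). Lists of ATF4 and amino acid response genes and of xenobiotic response genes had medians of 0.11 and 0.13 (adjusted p = 0.0305 and 0.0349, and adjusted p = 0.754 and 0.709 with an estimated correlation). BMP-SMAD signalling, the pathway through which liver cells control the iron hormone hepcidin, was lower, with a median of -0.12 and 17 of 19 genes below 0 (adjusted p = 0.000969, and adjusted p = 0.339 with an estimated correlation). With the replicate block, BMP-SMAD signalling and heme synthesis and breakdown passed under an estimated correlation (adjusted p = 0.0298 for each). Cell cycle genes had a median of -0.07 and respiratory chain genes of -0.03, with 17 of 28 and 23 of 24 below 0 (adjusted p = 0.00583 and 0.0305, and adjusted p = 0.731 and 0.754 with an estimated correlation). Adjusted over the list alone, 0 members of these lists passed without the block except 1 of the xenobiotic response genes. The replicate block, adjusted over the list alone, gave 12 unfolded protein response genes, 4 fatty acid synthesis genes, 4 heme genes, 4 ATF4 genes and 2 xenobiotic response genes.

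These 10 lists became 6 without alone replicate 1 and 6 without FAC replicate 3. Such fits, without the block, also carry differences between replicate numbers. Without alone replicate 1 the medians were 0.09 for the unfolded protein response, 0.05 for ATF4 and amino acid response, 0.04 for xenobiotic response, 0.09 for fatty acid synthesis and 0.14 for NRF2 targets. Without FAC replicate 2 the first 3 of these were 0.10, 0.04 and 0.05. Without FAC replicate 3 the medians were 0.04 for ATF4 and amino acid response, 0.05 for xenobiotic response, -0.08 for BMP-SMAD signalling and 0.09 for heme synthesis and breakdown. They rose to 0.44 for the unfolded protein response and 0.23 for ATF4 and amino acid response without FAC replicate 1, and to 0.19 for ATF4 and amino acid response and 0.24 for fatty acid synthesis without alone replicate 3. For cell cycle the median was -0.10 without alone replicate 2. Without alone replicate 1 the lists that missed the threshold were the unfolded protein response (adjusted p = 0.322), ATF4 and amino acid response (0.420), cell cycle (0.290) and xenobiotic response (0.376). Without FAC replicate 2 they were these lists at 0.209, 0.904, 0.170 and 0.337, and heme synthesis and breakdown at 0.0727. Without FAC replicate 3 they were ATF4 and amino acid response (0.361), BMP-SMAD signalling (0.0564), respiratory chain (0.0775) and xenobiotic response (0.122), and the respiratory chain list also missed it without alone replicate 2 (0.285) or FAC replicate 1 (0.188). In all, 12 lists passed with the replicate block, the acute phase and ferroptosis-related lists being added (adjusted p = 0.0114 and 0.0240, and adjusted p = 0.0888 and 0.125 with an estimated correlation).

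The iron handling list was not called with FAC, with a median of 0.02 over 25 genes (adjusted p = 0.332). The test looks for a shift in 1 direction, so members that move in opposite directions can cancel. Tfrc was its 1 lower gene adjusted over the list alone, against 0 over all genes, and with the replicate block Cp and Ncoa4 also passed over the list alone. In the average effect of iron with the block, these 2 were higher over all genes and 1 member was lower. Fth1, the ferritin heavy chain, differed by 0.04 ± 0.07 (SE without the block) at values between 14.23 and 14.41, close to the highest gene value of 14.56, which limits what this gene can show in each comparison. The iron exporter gene Slc40a1 differed by 0.21 ± 0.09, the iron importer gene Slc11a2 by -0.17 ± 0.07 (its 4 probe sets from -0.41 to 0.01) and Hamp, which encodes hepcidin, by 0.06 ± 0.07. Bmp6, Id1 and Smad7 differed by -0.10 ± 0.10, -0.17 ± 0.19 and -0.20 ± 0.17. Lcn2, an iron-siderophore binding protein, and Saa3, an acute phase protein, had values of 0.42 ± 0.37 and 0.65 ± 0.32, and Ccl2, Il6, Lyz2, Cd68 and Alb lay between -0.15 and 0.11. Apart from Tfrc, which passed with the replicate block, none of the genes named here passed over all genes between FAC and alone in limma, with or without the block. The ferritin light chain gene Ftl1 was not analysed here because its probe set names several genes.

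**Figure D1:**
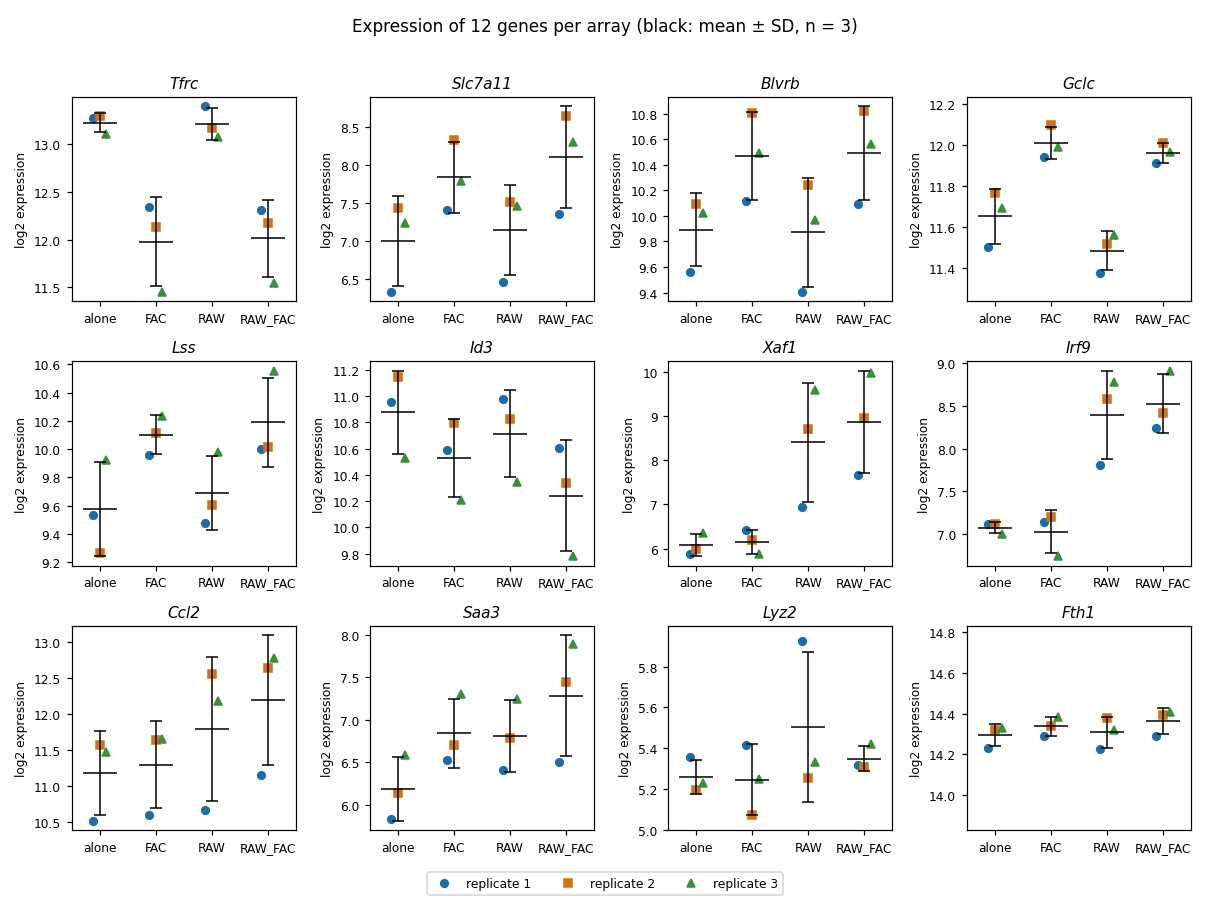
Log2 expression (vertical axis) of 12 genes on each of the 12 arrays by group (horizontal axis), with a colour and a symbol per replicate number and the group mean ± SD (n = 3) in black. Tfrc lies between 11.46 and 12.35 on the 6 arrays with FAC and between 13.07 and 13.40 on the 6 without, and Irf9 between 7.81 and 8.91 on the 6 arrays with macrophages and between 6.74 and 7.20 on the 6 without.

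Iron in the presence of macrophages was assessed by comparing RAW_FAC with RAW. Tfrc fell by 1.20 ± 0.13 (SE with the replicate block), 2.29-fold, and Slc7a11 rose by 0.95 ± 0.11, 1.94-fold. Blvrb rose by 0.62 ± 0.06, Slc48a1 by 0.58 ± 0.07 and Gclc by 0.48 ± 0.05. Among the remaining genes, Cp, the copper-binding ferroxidase ceruloplasmin, rose by 0.53 ± 0.08 and Lbp, a lipopolysaccharide-binding protein, by 0.56 ± 0.08. Reep6, Mettl7b, Adh7, Sqor and Chpf2 rose by between 0.37 and 0.55. Lce1i, a cornified envelope gene, fell by 0.83 ± 0.09 and Adam12, a metalloprotease, by 0.65 ± 0.08. Each of these 14 genes moved the same way in 3 of 3 same-number pairs. Over their probe sets the change went from 0.28 to 0.95 for Slc7a11, 0.06 to 0.73 for Cp, 0.35 to 0.56 for Lbp, 0.02 to 0.37 for Chpf2 and 0.11 to 0.42 for Sqor, and from -1.32 to -0.25 for Tfrc and -0.65 to -0.17 for Adam12. Without RAW replicate 1, and without the block, the difference was 0.61 for Slc7a11, 0.39 for Blvrb, 0.30 for Adh7, 0.24 for Cp and 0.16 for Sqor. It was 0.80 for Cp and 0.69 for Sqor without RAW_FAC replicate 1, 0.24 for Sqor without RAW_FAC replicate 2 and 0.36 for Reep6 without RAW_FAC replicate 3. Differences between replicate numbers enter these values too.

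The 11 higher and 3 lower genes passed in limma with the replicate block (adjusted p from 0.0145 to 0.0434) and were chosen after the values were seen. As for FAC against alone, their SE and adjusted p may be too small. Without the block limma called 0 of 18194 genes, 1038 having an unadjusted p under 0.05, and with it 2029 did. The smallest adjusted p without the block was 0.556, and the 10 genes with the smallest p there, not passing, were Gclc, Csgalnact1, Tfrc, Pnldc1, Scn3a, Chpf2, Adam12, C8g, Pfkfb4 and Ccng2. The blocked count of 11 higher genes became 0 without RAW replicate 1, RAW replicate 2 or RAW_FAC replicate 2, 1 without RAW_FAC replicate 3, 4 without RAW replicate 3 and 7 without FAC replicate 2. The 3 lower genes became 0 without RAW replicate 1, RAW replicate 2 or RAW_FAC replicate 2, 1 without RAW_FAC replicate 1 or RAW_FAC replicate 3, and 5 without alone replicate 2.

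Next to macrophages, NRF2 targets had a median change with iron of 0.27 and cholesterol synthesis genes of 0.35, with 21 of 21 and 20 of 20 genes above 0 (limma camera adjusted p = 4.04e-14 and 2.11e-13, and adjusted p = 0.353 and 0.405 with an estimated correlation). Adjusted over the list alone 6 and 8 of their genes passed, against 0 over all genes. With the block 16 and 18 passed over the list alone, and Slc7a11 and Gclc over all genes. Mvd changed by 0.67 ± 0.21 and Dhcr7, a late enzyme of cholesterol synthesis, by 0.52 ± 0.15 (SE without the block). The unfolded protein response list had a median of 0.28 (adjusted p = 4.75e-06, and adjusted p = 0.905 with an estimated correlation), and its member Sdf2l1, a partner of endoplasmic reticulum chaperones, changed by 0.64 ± 0.36. Xenobiotic response genes had a median of 0.21 (adjusted p = 0.000520, and adjusted p = 0.353 with an estimated correlation), led by Aldh3a1, an aldehyde dehydrogenase, at 0.83 ± 0.42.

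Fatty acid synthesis genes had a median of 0.19 and ATF4 and amino acid response genes of 0.16 (adjusted p = 0.00408 and 0.00629, and adjusted p = 0.905 for each with an estimated correlation). Heme synthesis and breakdown had a median of 0.09 (adjusted p = 0.00409, and adjusted p = 0.270 with an estimated correlation). BMP-SMAD signalling was lower, with a median of -0.12 and 17 of 19 genes below 0 (adjusted p = 0.000631, and adjusted p = 0.353 with an estimated correlation). Its members Id1 and Id3, transcription regulators that BMP signals induce, and Smad7, which restrains the pathway, had changes of -0.32 ± 0.19, -0.47 ± 0.23 and -0.27 ± 0.17. With the replicate block, NRF2 targets, xenobiotic response and BMP-SMAD signalling passed under an estimated correlation (adjusted p = 0.0249 for each), as did heme synthesis and breakdown (adjusted p = 0.0293). Adjusted over the list alone the block gave 16 unfolded protein response, 9 fatty acid synthesis, 7 xenobiotic response, 6 ATF4 and 5 heme genes higher, and 5 BMP-SMAD genes lower. The block added NF-kB response and acute phase genes (adjusted p = 0.0128 and 0.00443, and adjusted p = 0.328 and 0.0940 with an estimated correlation), which made 10 lists.

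The 8 lists shifted with iron beside macrophages became 4 without RAW_FAC replicate 2 and 5 without RAW_FAC replicate 3. For the unfolded protein response the median was 0.13 without RAW replicate 1, 0.14 without RAW_FAC replicate 2 and 0.46 without RAW_FAC replicate 1. For ATF4 and amino acid response it was 0.03, 0.05 and 0.34 without these arrays, and 0.08 without RAW_FAC replicate 3. Fatty acid synthesis had 0.10 without RAW_FAC replicate 3, and heme synthesis and breakdown 0.13 without RAW_FAC replicate 1. Without RAW_FAC replicate 2 the lists that missed the threshold were ATF4 and amino acid response (adjusted p = 0.880), the unfolded protein response (0.196), heme synthesis and breakdown (0.113) and xenobiotic response (0.0715). Without RAW_FAC replicate 3 they were ATF4 and amino acid response (0.322), fatty acid synthesis (0.121) and BMP-SMAD signalling (0.0635). Fatty acid synthesis also missed it without RAW replicate 1 (0.0675) or RAW replicate 2 (0.0628), and ATF4 and amino acid response without RAW replicate 1 (0.331). Fth1, Slc40a1, Slc11a2, Hamp and Bmp6 had values of 0.06, 0.18, -0.06, -0.08 and -0.05, and Hmox1 of 0.49 ± 0.30. The 4 probe sets of Slc11a2 ranged from -0.45 to 0.07. Lcn2, Saa3 and Ccl2 had values of 0.84 ± 0.37, 0.47 ± 0.32 and 0.40 ± 0.51, and Il6, Lyz2, Cd68 and Alb of -0.16, -0.15, 0.07 and -0.01. None of these genes passed in limma with or without the block.

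The comparison of RAW with alone asked which genes of the liver cells changed when macrophages sat in the insert. Xaf1, an interferon-induced regulator of cell death, had a change of 2.33 ± 0.59 (SE without the block), 5.02-fold, and Rtp4, an interferon-induced gene, of 2.17 ± 0.69, 4.51-fold. Usp18, which limits interferon signalling, had 1.34 ± 0.52, Irf9, a subunit of the transcription factor that interferon activates, 1.31 ± 0.22, and Trim21, a cytosolic antibody receptor, 0.74 ± 0.12. Each was higher in 3 of 3 same-number pairs. A second probe set of Xaf1 and of Rtp4 gave a change of 0.12 for each gene.

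In limma 0 of 18194 genes passed without or with the replicate block, the smallest adjusted p being 0.479 and 0.193, while 693 and 1115 genes had an unadjusted p under 0.05. The 10 genes with the smallest p without the block, not passing, were Trim21, Irf9, H60c, Spink1, Cxcl11, Gm11992, Mndal, Mycn, Pnldc1 and 0610040F04Rik. Without RAW replicate 1 the fit called 1 higher gene, Irf9 (adjusted p = 0.0179), and without RAW_FAC replicate 1 the blocked fit called 2. Ccl2, a monocyte-attracting chemokine, had a change of 0.61 ± 0.51 and Saa3 of 0.62 ± 0.32. Hmox1, Lcn2, Il6 and Lyz2 had values of 0.13, 0.07, 0.06 and 0.24, and Tfrc, Fth1, Slc40a1, Slc11a2, Hamp, Bmp6, Id1, Smad7, Cd68 and Alb lay between -0.11 and 0.07.

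The interferon response list was higher next to macrophages, with a median of 0.16 and 24 of 30 genes above 0 (limma camera adjusted p = 2.23e-08, and adjusted p = 0.819 with an estimated correlation). Its medians in the 3 same-number pairs were 0.07, 0.25 and 0.33, and without RAW replicate 1 its median was 0.27. Over all genes 0 of its members passed, and adjusted over the list alone 8 were higher and 1, Ifi27l2a, was lower, or 12 and 1 with the replicate block. Antigen presentation genes had a median of 0.13 with 13 of 17 above 0 (adjusted p = 0.0404, and adjusted p = 0.819 with an estimated correlation). They lost the call without alone replicate 1 (adjusted p = 0.0804), alone replicate 2 (0.0580), alone replicate 3 (0.0572), RAW replicate 2 (0.240) or RAW replicate 3 (0.149, with a median of 0.06). The count of 2 lists became 4 without alone replicate 1, 1 without alone replicate 2 or RAW replicate 2, and 6 without RAW replicate 1. The replicate block gave 4 lists, adding chemokines upward and xenobiotic response downward, with medians of 0.14 and -0.08 (adjusted p = 8.88e-05 and 0.0201, and adjusted p = 0.336 for each with an estimated correlation). Those 4 became 9 without alone replicate 1, 7 without alone replicate 2 and 2 without RAW replicate 2.

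Macrophages in the presence of iron were assessed by comparing RAW_FAC with FAC. Of the interferon-induced genes, Xaf1 had a change of 2.70 ± 0.59 (SE without the block), 6.51-fold, Rtp4 2.44 ± 0.69, Usp18 1.58 ± 0.52, Mndal, an interferon-inducible DNA-sensing family gene, 1.33 ± 0.28 and Igtp, an immunity-related GTPase gene, 0.95 ± 0.23, and Irf9 differed 2.82-fold. Each was higher in 3 of 3 same-number pairs. The second probe sets of Xaf1 and Rtp4 gave -0.12 and -0.08. The chemokine genes Ccl2 and Ccl7 had changes of 0.90 ± 0.51 and 0.79 ± 0.44.

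Without or with the replicate block limma called 0 of 18194 genes between RAW_FAC and FAC, the smallest adjusted p being 0.265 and 0.0661, with 574 and 1020 genes at an unadjusted p under 0.05. The 10 genes with the smallest p without the block, not passing, were Irf9, Trim21, Mndal, Eif2ak2, Xaf1, Cxcr5, Gm31981, Igtp, Irgm1 and 4932437C15Rik. Leaving out RAW replicate 1 gave 1 higher gene, Irf9 (adjusted p = 0.0117), and leaving out RAW_FAC replicate 1 gave 3 with the block. The interferon response list had a median of 0.27 with 24 of 30 genes above 0 (limma camera adjusted p = 2.55e-13, and adjusted p = 0.626 with an estimated correlation), and medians of 0.12, 0.25 and 0.53 in the same-number pairs. Without RAW_FAC replicate 3 its median was 0.15. Adjusted over the list alone 11 of its genes passed, or 15 with the block, against 0 over all genes. NF-kB response genes had a median of 0.08 with 18 of 21 above 0 (adjusted p = 4.34e-05, and adjusted p = 0.661 with an estimated correlation), and lost the call without RAW_FAC replicate 2 (adjusted p = 0.0643). Their median was 0.16 without FAC replicate 2 and 0.21 without RAW_FAC replicate 1. Their member Nfkbie, an inhibitor of NF-kB, had a change of 0.60 ± 0.23. The 2 lists became 6 without FAC replicate 2 and 7 without RAW_FAC replicate 1. With the block 4 passed, chemokines and antigen presentation being added (adjusted p = 5.49e-05 and 0.0432, and adjusted p = 0.184 and 0.627 with an estimated correlation), and those 4 became 11 without RAW_FAC replicate 1. Lcn2, Saa3, Hmox1, Hamp, Alb and Id1 had values of 0.50 ± 0.37, 0.44 ± 0.32, 0.13, -0.12, -0.12 and -0.18, and Tfrc, Fth1, Slc40a1, Slc11a2, Bmp6, Smad7, Il6, Lyz2 and Cd68 lay between -0.11 and 0.10. Over their probe sets Tfrc ranged from -0.09 to 0.18, Slc11a2 from -0.01 to 0.22 and Smad7 from -0.33 to -0.11.

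**Figure D2:**
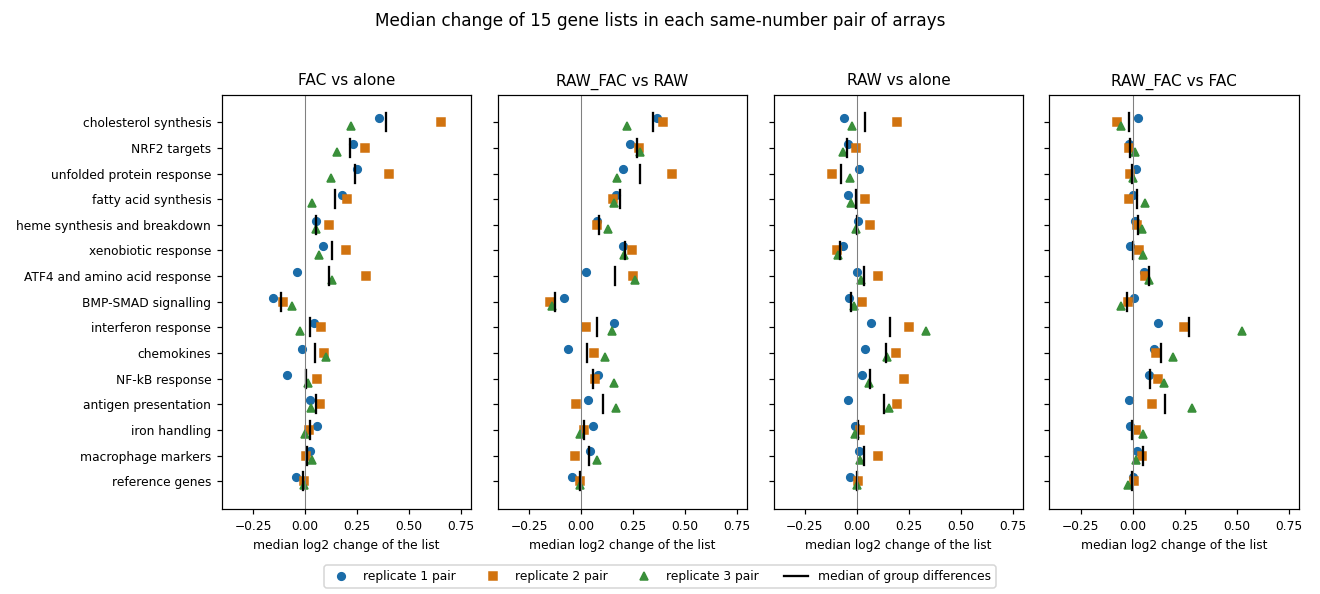
Median log2 change (horizontal axis) of 15 gene lists (vertical axis) in 4 comparisons, with a coloured symbol per same-number pair of arrays and a black bar for the median of the group differences. Cholesterol synthesis and NRF2 targets lie above 0 in each of the 6 pairs with iron, and the interferon response list lies above 0 in each of the 6 pairs with macrophages.

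Both treatments together were assessed by comparing RAW_FAC with alone. Irf9 rose with the replicate block by 1.45 ± 0.22, 2.73-fold, and Mndal by 1.49 ± 0.23. The chemokine genes Ccl20 and Ccl2 rose by 1.29 ± 0.17 and 1.01 ± 0.15, Slc7a11 2.14-fold, Saa3 by 1.09 ± 0.12 and Osmr, the oncostatin M receptor, by 0.77 ± 0.12. Tfrc fell by 1.21 ± 0.13, Egr1, an immediate early transcription factor, by 0.69 ± 0.11 and Id3 by 0.63 ± 0.09. Prg4, Trim21, Slc39a4, Slc48a1, Lss, Blvrb and Hpx rose by between 0.48 and 0.74, and Lce1i, Adam12, Ppbp, Efnb2, Dbp, Cpeb2 and Tlr1 fell. Each gene named here moved the same way in 3 of 3 same-number pairs. Of the 3 probe sets of Osmr, 1 was higher and the lowest gave -0.18, and of the 4 of Efnb2, 3 were lower and the highest gave 0.13. The smallest change of a probe set was 0.48 for Slc7a11, 0.38 for Trim21, 0.13 for Lss, -0.23 for Tfrc, -0.19 for Adam12, -0.20 for Dbp and -0.27 for Cpeb2. Without the block, the difference without RAW_FAC replicate 1 was 1.53 for Ccl2, 1.11 for Prg4, 1.05 for Slc39a4 and 0.10 for Hpx, and for Ccl20 it was more than 1.5 times the 1.29 of all arrays. Without RAW_FAC replicate 2 it was 0.75 for Ccl20, 0.47 for Osmr, 0.40 for Prg4 and 0.73 for Hpx. Without RAW_FAC replicate 3 it was 0.42 for Slc39a4 and -0.40 for Id3. Without alone replicate 1 it was 0.84 for Ccl20, 0.33 for Prg4 and 0.95 for Hpx. It was 0.19 for Hpx and -0.39 for Lce1i without alone replicate 2, and 0.32 for Hpx without alone replicate 3. Differences between replicate numbers enter these values as well. Lcn2 had a value of 0.92 ± 0.37, Hmox1 of 0.63 ± 0.30 and Id1 of -0.35 ± 0.19 (SE without the block), and Fth1, Slc40a1, Slc11a2, Hamp, Bmp6, Smad7, Il6, Lyz2, Cd68 and Alb lay between -0.30 and 0.25, none passing with or without the block. Over their probe sets Slc11a2 ranged from -0.42 to 0.13 and Smad7 from -0.47 to -0.30.

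In limma 26 genes were higher and 11 lower between RAW_FAC and alone with the replicate block, the smallest adjusted p being 0.00824, and they were chosen after the values were seen. Here too the blocked SE and adjusted p may be too small, as arrays with and without iron are compared. Without the block 0 genes passed (smallest adjusted p = 0.192), 887 having an unadjusted p under 0.05 against 1840 with the block. The 10 genes with the smallest p without the block, not passing there, were Irf9, Dbp, Trim21, Tfrc, Cyp26b1, Tspyl4, Mndal, Gm3363, Csgalnact1 and Slc26a6, and without RAW replicate 1 Irf9 passed (adjusted p = 0.0163). The blocked 26 became 0 without alone replicate 2, RAW_FAC replicate 2 or RAW_FAC replicate 3, and 4 without alone replicate 3. They became 12 without FAC replicate 2, 17 without FAC replicate 3, 15 without RAW replicate 2 and 11 without RAW replicate 3. The blocked 11 became 0 without alone replicate 2, RAW_FAC replicate 2 or RAW_FAC replicate 3, 1 without alone replicate 3, and 4 without alone replicate 1 or RAW replicate 3. They became 5 without FAC replicate 3 or RAW_FAC replicate 1, and 6 without FAC replicate 2 or RAW replicate 2.

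Of the gene lists 14 shifted between RAW_FAC and alone. Cholesterol synthesis, interferon response and NRF2 targets had medians of 0.38, 0.19 and 0.24, with 20 of 20, 24 of 30 and 18 of 21 genes above 0 (limma camera adjusted p = 1.36e-16, 1.34e-11 and 6.34e-10, and adjusted p = 0.249 for each with an estimated correlation). Adjusted over the list alone 9, 11 and 6 of their genes passed, against 0 over all genes. The unfolded protein response and ATF4 lists had medians of 0.26 and 0.20 (adjusted p = 0.000254 and 0.000945, and adjusted p = 0.608 for each with an estimated correlation). NF-kB response, antigen presentation and chemokines had medians of 0.11, 0.16 and 0.08 (adjusted p = 0.00121, 0.00377 and 0.00797, and adjusted p = 0.376, 0.284 and 0.206 with an estimated correlation). Vcam1, a leukocyte adhesion molecule of the NF-kB list, had a change of 1.07 ± 0.38 (SE without the block), and its 3 probe sets ranged from 0.09 to 1.07. Fatty acid synthesis, xenobiotic response and heme synthesis and breakdown had medians of 0.20, 0.11 and 0.09 (adjusted p = 0.00418, 0.0214 and 0.00199, and adjusted p = 0.554, 0.378 and 0.206 with an estimated correlation). BMP-SMAD signalling was lower, with a median of -0.11 (adjusted p = 3.47e-05, and adjusted p = 0.232 with an estimated correlation). With the replicate block 6 of its genes, Id1, Id2, Id3, Smad6, Smad7 and Atoh8, were lower adjusted over the list alone, against Id3 over all genes. Cell cycle and respiratory chain genes had medians of -0.08 and -0.03 (adjusted p = 0.0199 and 0.0382, and adjusted p = 0.554 and 0.608 with an estimated correlation). Under an estimated correlation with the block, BMP-SMAD signalling and heme synthesis and breakdown passed (adjusted p = 0.0363 and 0.0465). The block made 17 lists, adding acute phase, metallothionein and ferroptosis-related genes (adjusted p = 0.00178, 0.0278 and 0.0384, and adjusted p = 0.0646, 0.230 and 0.16 with an estimated correlation).

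The 14 lists became 9 without alone replicate 1 and 5 without RAW_FAC replicate 2. For the unfolded protein response the median was 0.07 without alone replicate 1, 0.08 without RAW_FAC replicate 2 and 0.43 without RAW_FAC replicate 1. Without RAW_FAC replicate 1 it was 0.37 for ATF4 and amino acid response, 0.26 for antigen presentation and 0.30 for interferon response. Without RAW_FAC replicate 2 it was 0.11 for ATF4 and amino acid response, 0.10 for antigen presentation, 0.07 for NF-kB response and -0.04 for cell cycle. Without RAW_FAC replicate 3 it was 0.10 for ATF4 and amino acid response and 0.11 for fatty acid synthesis. Cell cycle had -0.04 without alone replicate 1 and -0.05 without alone replicate 3, where chemokines had 0.14 and fatty acid synthesis 0.31. Without alone replicate 2 cholesterol synthesis had 0.24 and fatty acid synthesis 0.09. Without alone replicate 1, cell cycle (adjusted p = 0.293), fatty acid synthesis (0.110), respiratory chain (0.0596), the unfolded protein response (0.326) and xenobiotic response (0.179) missed the threshold. Without RAW_FAC replicate 2, ATF4 and amino acid response (0.339), NF-kB response (0.110), antigen presentation (0.0806), cell cycle (0.339), chemokines (0.161), heme synthesis and breakdown (0.0669), respiratory chain (0.0669), the unfolded protein response (0.459) and xenobiotic response (0.342) did. Without RAW_FAC replicate 3, ATF4 and amino acid response (0.0700), fatty acid synthesis (0.0865), respiratory chain (0.109) and xenobiotic response (0.0613) did. Fatty acid synthesis (0.107) and respiratory chain (0.189) also missed it without alone replicate 2, and respiratory chain (0.114) without RAW_FAC replicate 1.

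Whether the effect of iron differed with and without macrophages was tested as the interaction, which is also the test of whether the effect of macrophages differed with and without iron. For Tfrc the difference between the iron effects was 0.05 ± 0.30 (SE without the block), and for Xaf1 the difference between the macrophage effects was 0.38 ± 0.83. In limma 0 of 18194 genes passed without or with the replicate block (smallest adjusted p = 1.00 and 0.999), with 540 and 790 genes at an unadjusted p under 0.05. The 10 genes with the smallest p, not passing, were Nhlh2, Vwa2, Ing4, Etohd2, H60c, Abca14, Trim71, Fam124b, Cyp3a11 and Scg3. The list test, added after the data were seen, called 0 lists with limma camera without or with the block (smallest adjusted p = 0.576 and 0.136). It called 1 without alone replicate 1, RAW replicate 2 or RAW replicate 3, 2 without alone replicate 3 or FAC replicate 2, and 6 without RAW_FAC replicate 1. With the block it called 1 without alone replicate 2, FAC replicate 1 or RAW replicate 1, and 2 without alone replicate 3 or RAW_FAC replicate 1.

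Across the 18194 genes, which are not independent replicates, the iron effects without and with macrophages had a Pearson r of 0.369 and a Spearman rho of 0.248, and 58.8% of genes had the same sign. The macrophage effects without and with iron had an r of 0.274 and a rho of 0.10, with 53.4% of genes of the same sign. Without the genes below the median level r was 0.680 and 0.535. These are 2 relations of 1 family, for which no p was computed. Over single pairs, iron effects with the same replicate number had a mean r of 0.256 and those with different numbers of 0.0974. For macrophage effects the means were 0.132 and 0.113.

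**Figure D3:**
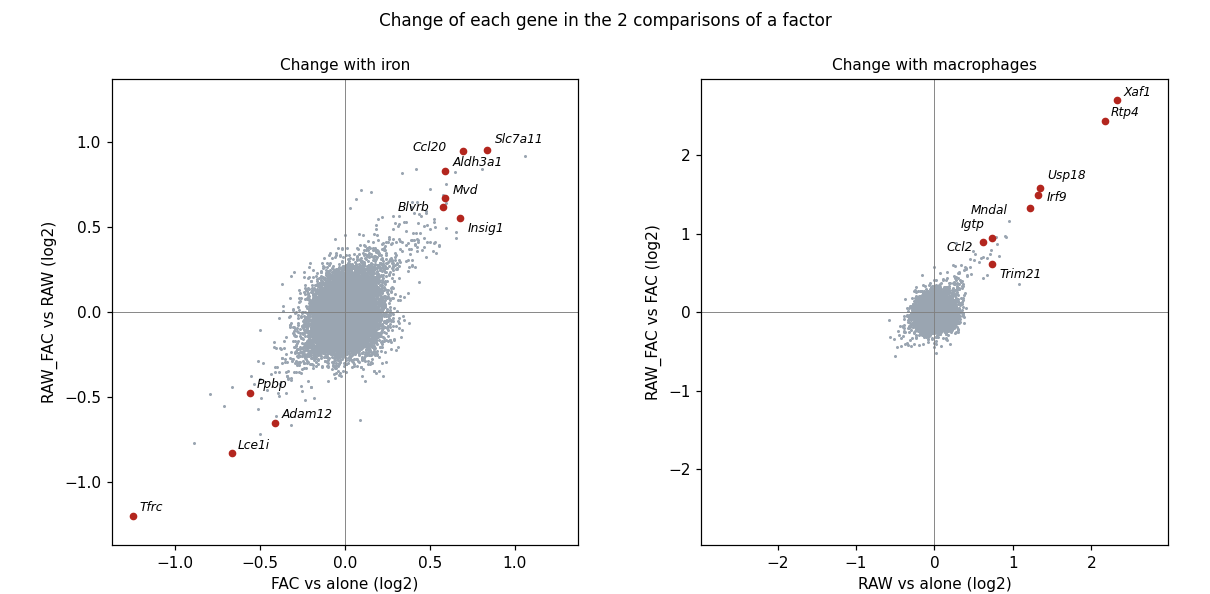
Log2 change of each of 18194 genes (grey points) with iron, without macrophages on the horizontal axis and with them on the vertical axis (left), and with macrophages, without iron on the horizontal axis and with it on the vertical axis (right), with selected genes in red. Tfrc and Slc7a11 lie near the diagonal in the left panel, at -1.25 and -1.20 and at 0.83 and 0.95, and Xaf1 in the right panel, at 2.33 and 2.70.

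Macrophage markers were followed in the liver cell samples as a sign of RNA from the insert. The list of 20 markers had medians of 0.01 in FAC against alone, 0.04 in RAW against alone, 0.07 in RAW_FAC against alone, 0.04 in RAW_FAC against RAW and 0.05 in RAW_FAC against FAC. In FAC against alone the median was -0.02 without alone replicate 2, and in RAW_FAC against RAW it was -0.01 without RAW replicate 1 or RAW replicate 3 and just below 0 without RAW_FAC replicate 3. The list passed in none of the 5 comparisons (limma camera adjusted p between 0.178 and 0.836), and in RAW_FAC against RAW the test's direction was downward while median and mean were above 0. Tyrobp, a signalling adaptor of myeloid cells, was lower there adjusted over the list alone, with a change of -0.25 ± 0.06, against 0 genes over all genes. Lyz2, the lysozyme of macrophages, had a change of 0.24 ± 0.14 and Cd68, a macrophage lysosomal protein, of 0.03 ± 0.14 in RAW against alone. The difference between the 3 prime and 5 prime control probe sets of Gapdh and Actb, a sign of RNA quality, differed between groups by at most 0.04 in size, with two-sided exact permutation p between 0.3 and 0.9 for n = 3 per group. Adjusted by Benjamini-Hochberg over the 10 tests they lay between 0.875 and 0.9, and the smallest p that 3 arrays against 3 allow is 0.1. These control probe sets lay between 13.68 and 14.50, close to the highest gene value of 14.56, which limits the measure. The Gapdh difference also followed the replicate number, at -0.05 to -0.03 on arrays numbered 2 and 0.06 to 0.11 on those numbered 3. The permutation tests left the number out, which widens the spread within groups.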

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

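The tests of the interaction on gene lists, of RNA from macrophages, of a single array, of RNA quality and of shared variation, and the fits with the replicate block combined with another choice, were tests chosen only after the results were seen. For 2 lists that passed in neither comparison, the medians of the same-number pairs had opposite signs without and with iron. The ferroptosis-related list was below 0 in 3 of 3 pairs of RAW and alone and above 0 in 3 of 3 pairs of RAW_FAC and FAC, the middle values lying 0.0460 apart, but its medians of the group differences were 0.01 and 0.02. The p53 targets had the same signs, 0.0437 apart. The limma camera test of the interaction on these lists, which compares their mean shift with that of other genes, called neither (adjusted p = 0.898 and 0.718, and 0.972 and 0.546 with the replicate block). The difference of medians itself was not tested.

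Interferon response genes were higher with macrophages. RNA from macrophages may have reached the liver cell samples, but the interferon median exceeded the macrophage marker median by 0.223 on average (SD 0.167), in 6 of 6 same-number pairs, which argues against it as the whole cause. The marker median was itself above 0 in 6 of 6 pairs (0.01 to 0.10), with 16 of 20 markers above 0 and the highest change 0.21, so a small contribution stays open. A single array is argued against as the whole cause, since the interferon median was at least 0.13 with any array left out. The highest limma camera adjusted p was then 0.00219, at the preset correlation of 0.01, which allows little for shared variation. The median still moved from 0.27 to 0.15 without RAW_FAC replicate 3 in RAW_FAC against FAC and from 0.16 to 0.27 without RAW replicate 1 in RAW against alone. A response of the liver cells to macrophages stays open as a hypothesis, since shared variation between interferon genes was not excluded (adjusted p = 0.819 and 0.626 with an estimated correlation).

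NRF2 targets were higher with iron. RNA quality could shift many genes together and cannot be told apart from a response: the difference between 3 prime and 5 prime control probe sets was higher with iron in 3 of 6 same-number pairs, with changes of -0.02 to 0.02 in probe sets near the top of the scale. Variation shared by the genes of the list is argued against with the replicate block, where the larger adjusted p under an estimated correlation was 0.0298, while without the block it was 0.353. The blocked value may be too small, since same-number residuals correlated more within an iron condition than across. A response to iron remains a hypothesis, found and tested on the same data.

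Cholesterol synthesis genes were higher with iron. RNA quality could be a cause and stays open for the same reason, with the same 3 of 6 pairs. Variation shared by these genes cannot be told apart from a response to iron, because with the replicate block the larger adjusted p under an estimated correlation was 0.183.

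The 6 arrays of a comparison can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. For genes without the block, 10 of 10 splits gave as many as the real 0 in each of the 5 comparisons, and the highest other count was 0, or 1 for RAW_FAC and FAC. With the replicate block, the real counts for FAC and alone, RAW_FAC and alone, and RAW_FAC and RAW were 6, 37 and 14, each reached in 1 of 10 splits with a highest other of 0. For RAW and alone and for RAW_FAC and FAC they were 0, reached in 10 of 10 splits with a highest other of 0. For lists, FAC and alone gave 10 (reached in 3 splits, highest other 11), RAW and alone 2 (8 splits, 12), RAW_FAC and alone 14 (2 splits, 14), RAW_FAC and RAW 8 (3 splits, 13) and RAW_FAC and FAC 2 (7 splits, 14). With the block these were 12 (1 split, 11), 4 (7 splits, 11), 17 (2 splits, 18), 10 (2 splits, 13) and 4 (4 splits, 7). Among the 4 splits that part the 3 same-number pairs, the highest other list counts were 5, 2, 9, 4 and 2 without the block and 6, 4, 18, 6 and 3 with it. The remaining splits put both arrays of some pair in one group.

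For the interaction, 100 of 100 regroupings of the 12 arrays gave as many genes and lists as the real 0, with and without the block. Any regrouping reaches a count of 0, so this decides nothing about chance. The highest other counts were 579 genes and 16 lists without the block and 205 genes and 15 lists with it. The regroupings mix treatments and replicate numbers, and the one with 579 genes gave 0 with the block. The source of these counts was not tested.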

How the results depend on the processing

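The tests of the replicate block combined with a further choice and the tests of the average effects were chosen only after the results were seen. No list past the threshold without the block, and no named gene past it with or without the block, changed sign under the alternatives in which signs were followed. Named genes that had not passed changed sign in 117 of 5656 instances. The fit to probe sets one by one was not among those followed for named genes. Probe sets of Sqor (-0.06 in FAC and alone), Osmr and Efnb2 (-0.18 and 0.13 in RAW_FAC and alone) had the sign opposite to the change reported. The signs of lists that passed only with the block were not followed. Of the counts, marker levels and correlations, 693 stayed within their limits and 178 moved, and lists kept their call in 482 instances and lost it in 130. The 693 include gene counts of 0 that stayed 0. No named gene had a call without the block to lose. Named genes stayed without one in 6565 instances and gained one in 49, of which 46 were with the replicate block. With the replicate block, FAC and alone had 4 higher and 2 lower genes, RAW_FAC and alone 26 and 11, and RAW_FAC and RAW 11 and 3, and the lists numbered 4 for RAW and alone and 4 for RAW_FAC and FAC. With an estimated correlation or with fry 0 lists passed in each of the 5 comparisons. With the block and an estimated correlation 3 passed for FAC and alone, 0 for RAW and alone, 2 for RAW_FAC and alone, 4 for RAW_FAC and RAW, 0 for RAW_FAC and FAC, 4 for the average effect of iron and 0 for that of macrophages. With the block and fry they were 7 for FAC and alone, 0 for RAW and alone and 0 for RAW_FAC and FAC. With the block and dim genes left out, fewer genes tested, FAC and alone had 13 higher, RAW_FAC and alone 76 and 30, RAW_FAC and RAW 64 and 12, and RAW_FAC and FAC 1 higher. With the block, trend and robust these were 35 and 5, 107 and 60, 108 and 27, and 2 higher, with 1 higher for RAW and alone. With the block and the mean of probe sets FAC and alone had 2 higher, RAW_FAC and alone 7 lower and RAW_FAC and RAW 7 higher, and with the block and quantile normalization FAC and alone had 1 lower and RAW_FAC and FAC 1 higher. Without dim genes RAW_FAC and FAC had 4 lists, the correlations of effects were 0.680 for iron and 0.535 for macrophages, the average effect of iron had 229 higher and 104 lower genes, and that of macrophages 2 lower. With trend and robust the average effects had 250 and 131, and 19 and 4. Without the block they had 0 and 1 for iron and 2 higher for macrophages, and with quantile normalization iron had 44 lower. The cause was not tested. With each array left out in turn, lists ranged from 6 to 14 for FAC and alone, 1 to 6 for RAW and alone, 5 to 16 for RAW_FAC and alone, 4 to 10 for RAW_FAC and RAW, 2 to 7 for RAW_FAC and FAC, 0 to 6 for the interaction and 4 to 10 for the average effect of macrophages. With the block they ranged from 2 to 9 for RAW and alone, 3 to 11 for RAW_FAC and FAC and 0 to 2 for the interaction. Higher genes ranged from 0 to 1 for RAW and alone, RAW_FAC and alone, and RAW_FAC and FAC. With the block, higher and lower genes ranged from 0 to 3 and 0 to 1 for FAC and alone, 0 to 29 and 0 to 14 for RAW_FAC and alone, and 0 to 15 and 0 to 5 for RAW_FAC and RAW, and higher genes from 0 to 2 for RAW and alone and 0 to 3 for RAW_FAC and FAC. The average effects ranged from 37 to 88 higher and 7 to 23 lower for iron, and 0 to 24 and 0 to 4 for macrophages. In data simulated at this size, 68% of log2 changes of 0.5 were recovered without the block and 82% with it. Larger changes planted in the same data ease the adjusted p of these genes, so the real fits may recover fewer.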

Other observations

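The tests of average effects, their alternatives and the swaps of whole replicate numbers were tests chosen only after the results of the separate comparisons were seen. The average effect of iron over both comparisons, in limma with the replicate block, covered 6 same-number pairs. Tfrc fell by 1.22 ± 0.09 (SE), 2.33-fold, Slc7a11 rose by 0.89 ± 0.08 and the glutathione transferase gene Gsta2 by 0.99 ± 0.12, each the same way in 6 of 6 pairs. Ccl20, Aldh3a1, Calr3 and Pate14 rose by 0.82, 0.71, 0.68 and 0.64. Mvd, Insig1 and the endoplasmic reticulum gene Sdf2l1 rose by 0.63, 0.62 and 0.62, and Lce1i, Selp and Sprr1b fell by 0.75, 0.61 and 0.55. In all, 116 genes were higher and 28 lower (smallest adjusted p = 0.00066), and 143 of the 144 had the same sign in 6 of 6 pairs. The genes were selected on these same pairs, which favours a shared sign. Without the block 0 were higher and 1, Tfrc, was lower, with 1185 genes at an unadjusted p under 0.05 against 2232 with it.

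The 116 higher genes with iron became 70 without alone replicate 1 or RAW replicate 1, 45 without alone replicate 2 or RAW replicate 2, 38 without FAC replicate 1, 37 without FAC replicate 2, 76 without FAC replicate 3, 74 without RAW replicate 3 and 40 without RAW_FAC replicate 2. The 28 lower genes became 14 without alone replicate 1, 9 without alone replicate 2, FAC replicate 1 or RAW_FAC replicate 2, 7 without FAC replicate 2, 13 without RAW replicate 1, 10 without RAW replicate 2 and 15 without RAW_FAC replicate 1. Of 32 sets of swaps within the 6 pairs, 1, the real one, gave 144 genes, and the highest other gave 0. The 6 pairs come from 3 replicate numbers, and iron effects of the same number correlated more (mean r 0.256) than those of different numbers (0.0974), so these swaps are not independent. For number 3 the r was 0.0347, within the range for different numbers (0.000727 to 0.173). Residuals of the same number also correlated more within an iron condition (median 0.431) than across (0.315). The SE and adjusted p of the average effect treat the pairs as separate and may be too small. Swapping whole numbers gives 4 sets, too few for a share under 0.05, of which 1 gave 144 genes with a highest other of 0. For the 11 lists shifted, 4 of the 32 gave as many and the highest other was 13, so chance is not excluded, and of the 4 sets 1 did, with a highest other of 8. NRF2 targets, BMP-SMAD signalling, heme synthesis and breakdown, and xenobiotic response passed with the block under an estimated correlation (adjusted p = 0.0163 for each), and cholesterol synthesis did not (0.0730). Without the block these 4 lists lost the call under an estimated correlation (adjusted p = 0.136, 0.136, 0.0872 and 0.236), where 0 lists passed. Over all genes 12 of 20 cholesterol synthesis genes and 11 of 21 NRF2 targets were higher, against 19 and 17 adjusted over the list alone.

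For the average effect of macrophages with the replicate block, limma called 10 genes higher and 0 lower, each higher in 6 of 6 pairs, with 1274 genes at an unadjusted p under 0.05. Xaf1 rose by 2.52 ± 0.34, Irf9 by 1.41 ± 0.15, Mndal by 1.27 ± 0.16, the RNA sensor genes Ddx58 and Ifih1 by 1.06 and 0.93, Ccl2 by 0.76 ± 0.11, and Trim21, Ccl7, Trim14 and Cxcl1 by 0.67, 0.64, 0.48 and 0.35. Without the block Irf9 and Trim21 passed. The 10 became 21 without alone replicate 1, 24 without RAW replicate 1, 22 without RAW_FAC replicate 1, 3 without FAC replicate 3, and 0 without alone replicate 2, alone replicate 3, FAC replicate 2, RAW replicate 2, RAW replicate 3, RAW_FAC replicate 2 or RAW_FAC replicate 3. The 0 lower genes became 3 without alone replicate 1, 1 without RAW replicate 1 and 4 without RAW_FAC replicate 1. Of 32 sets of swaps, 1, the real one, gave 10 genes and the highest other 0, and of the 4 sets that swap whole numbers 1 did, with a highest other of 0. The 4 sets are again too few for a share under 0.05. Macrophage effects of the same number correlated slightly more (mean r 0.132, from 0.0197 to 0.230) than those of different numbers (0.113, from -0.0420 to 0.263). The pairs share replicate numbers and the ranges overlap, so whether the 32 sets are independent stays open, and chance was not excluded. For the 6 lists, 3 of the 32 gave as many with a highest other of 7, so chance is not excluded, and 2 of the 4 did, with a highest other of 7. Of these lists, 0 of the 6 passed under an estimated correlation (interferon response adjusted p = 0.282), and without RAW replicate 3 there were 10.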
